A study of Zea mays with 8 samples.

How the data were processed

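Total RNA was extracted from bracts with Trizol, 6 µg were made into biotinylated cRNA, and an Affymetrix maize array was hybridised per sample, per the labels' protocols. The authors deposited linear intensity values, 1 signal per probe set and array. The signal algorithm and its version are not given in the sources used here. On every array the mean after trimming 2% from each end was about 500, so the deposited intensity values had been scaled between arrays, as seen from the values. No detection calls were used. The single-array values lie on a linear scale and between 17.4% and 19.0% of them were under 16.

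Samples were grouped by line and treatment as the labels state. Of 17734 probe sets, 113 array controls were left out and 17621 tested. Values were analysed as log2(value + 16), a scale that understates the change of dim probe sets. A mean per group was fitted over all 8 arrays with limma 3.58.1 in R 4.3.3, followed by eBayes with an intensity trend, which gave 4 residual and 3.24 prior degrees of freedom. Adjusted p is by Benjamini-Hochberg over all probe sets, with a threshold of 0.05. The 6 comparisons were infection in each line, their difference (interaction), the line difference in control and in infected bracts, and the mean infection effect. Figures were drawn with matplotlib 3.10.9.

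Gene names came from the platform annotation, updated by Entrez ID with the RefSeq gene table of Zm-B73-REFERENCE-NAM-5.0. In it 1452 probe sets had 1 gene, 1 had several and 16168 are unnamed here. They represent 1108 genes, of which 1060 matched the table and 980 had a usable name. The files name no genome build, so no coordinates are given. The order of genes along chromosomes, used only in the test of neighbouring genes, was taken from that RefSeq gene table.

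Of 29 gene lists fixed by name patterns before the data were examined, 21 had at least 5 genes. The table holds no descriptions, so only symbols and synonyms could be matched. Matches by synonym brought in unrelated genes, such as the hemoglobin GLB1 among the kernel markers and umi11 among the cell division genes. Lists were tested with camera (inter-gene correlation of 0.01, with a variance trend) against the 1108 annotated genes, taking the probe set with the highest mean per gene. The variance trend in camera was chosen after a run without it had been seen. With an estimated correlation 0 of 126 tests of lists passed, against 9 with the preset one. A larger correlation alone does not account for this loss. With an estimated correlation, camera also refers its statistic to the 4 residual degrees of freedom, which raises p at any correlation. A list that lost its pass in that run is therefore little evidence about correlation between its genes. For histones and cell division in control bracts the estimate was 0.0108, yet the unadjusted camera p went from 7.03e-05 to 0.0167. For terpenoid and phytoalexin synthesis in Bt-1 it was -0.0687, and p went from 0.00628 to 0.0449. The other lists that passed had larger estimates, from 0.0524 to 0.206.

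The named genes follow a rule fixed before the data were examined. It takes, per comparison, the 10 largest rises and the 10 largest falls among named probe sets past the threshold, where every array of one group lay beyond every array of the other. The mean effect and the interaction had no such condition. Where fewer than 5 probe sets passed it would have taken the 10 with the smallest p. It also takes, per list, the 2 members with the smallest p in either infection comparison. The probe set IDs without a gene name, a few list members and the values of the interaction were chosen after their values were seen.

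Simulated arrays had the real mean levels of 17621 probe sets and a spread drawn at random around the trend of replicate SD with mean level. In them 200 probe sets were changed in the Bt-1 infection comparison. Over 10 runs 21.4% of 2-fold and 84.3% of 4-fold changes were recovered, and 4.95% of the calls were false. The spread was not that of each real probe set, so recovery and the share of false calls on the real arrays may differ. Errors were drawn as normal, independent and alike in all groups, close to what the test assumes. A false share near the threshold was therefore likely from the start. Alternatives were quantile normalization, pseudocounts of 1 and 64, dropping the 33.3% of probe sets with the lowest mean, no intensity trend, the replicate number as a block, array weights, only the 4 arrays compared, a 2-fold minimum and each array left out, which leaves a lone array assumed to vary like the others. Scaling to 18 bacterial hybridisation control probe sets was added after the data had been seen. For the test of mixed RNA, bounds of 10 in Bt-1 and 1000 in Ye478 controls left 1 probe set, so 16 and 500 were set from control arrays alone, before the infected values of those probe sets were seen.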

Results

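Transcript levels were measured in maize bracts, the leaf-like husks around the ear, of Bt-1, an inbred line described as resistant to the ear-rot fungus Fusarium moniliforme, and of Ye478, a susceptible line. Bracts were injected with fungal spores when the kernels were at the milky stage and collected 4 days later. Uninfected plants of each line gave the control bracts, and the labels describe no injection of the controls with water, so the infection comparisons below do not separate the fungus from the wound of injection. No collection time is recorded for the control bracts, so a difference in time of collection is not separated from infection either. Each of the 4 groups held 2 arrays, which the labels call biological replicates, so the number of arrays limits the precision of every value. The probe-set signal had a median between 156 and 201 per array. Log2 signals of replicate arrays correlated at r = 0.964 to 0.979 across probe sets, those of different treatments of one line at 0.937 to 0.968, and those of different lines under one treatment at 0.895 to 0.918, where probe sets are not independent replicates. The first principal component held 53.2% of the variance. Only 1452 of the 17621 probe sets tested could be given 1 gene, so most of the counts below are of unnamed probe sets.

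The first comparison asked which transcripts differed between infected and control bracts of the resistant line. GLN6, a glutamine synthetase, rose from a signal of 142 ± 10.5 to 1814 ± 853 (SD, n = 2 arrays per group), a log2 change of 3.45 ± 0.34 (SE; limma adjusted p = 0.00994). The rise of bx6, an enzyme of benzoxazinoid synthesis, was 2.66 ± 0.33, from a control signal of 181 ± 38.6. One probe set of the glutathione transferase gst31 rose by 2.62 and FAD8, a fatty acid desaturase, by 2.54. Transcripts of starch and sucrose metabolism that rose were waxy1, the granule-bound starch synthase, by 2.68 from a control signal of only 2.93, and the sucrose synthase sh1 by 1.32. Of the list of that metabolism 2 of 17 genes rose and 0 fell, 4 passed adjusted over the list alone, 7 of 17 were positive with a median of -0.08, and the list did not pass (camera adjusted p = 0.887). The other named genes that rose were ARLC by 2.58, the cyclotide gene umi11 by 2.12, the cytokinin oxidase cko3 by 1.84 and the calcium-dependent protein kinase MCK2 by 1.80. A further probe set of cko3 had the opposite sign.

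Among the transcripts that were lower in infected Bt-1 bracts, xet1, a xyloglucan endotransglycosylase that remodels cell walls, went from 975 ± 44.4 to 71.4 ± 9.55 (SD, n = 2), a log2 change of -3.51 ± 0.33 (SE; limma adjusted p = 0.00881). The lysine-degrading enzyme lkrsdh1 changed by -2.11 and akh2, an aspartate kinase-homoserine dehydrogenase, by -1.95. GA20 changed by -1.96, lim1 by -1.64 and the aquaporin pip1e by -1.47. The silicon transporter Lsi1 changed by -1.46, and its 2 other probe sets had the opposite sign.

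**Figure D1:**
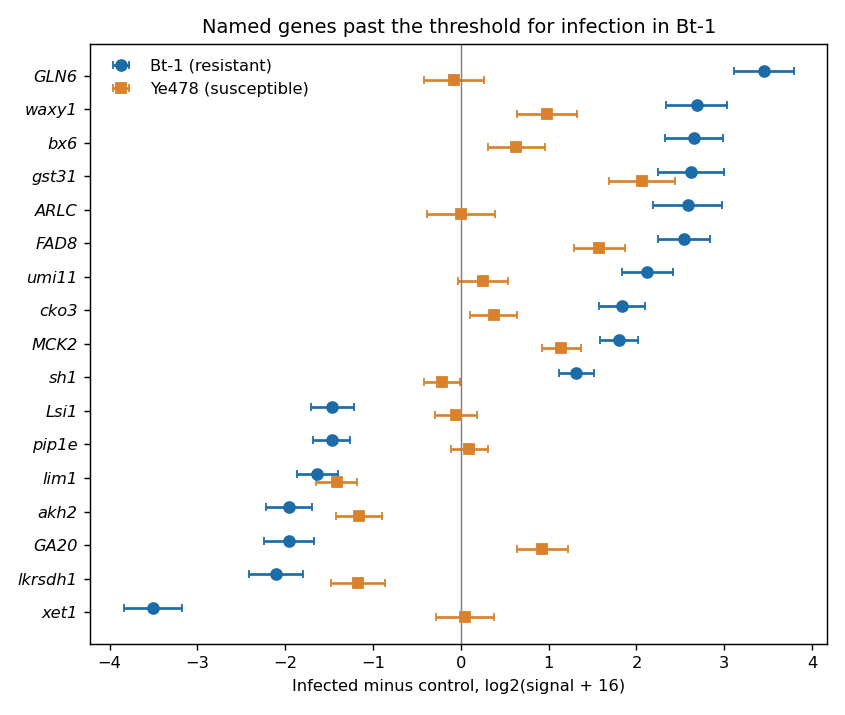
Log2 change of signal between infected and control bracts for the 17 named genes past the threshold in Bt-1, with the value in Bt-1 (circles) and in Ye478 (squares), and bars of 1 standard error from the limma fit over all 8 arrays. GLN6 stood at 3.45 in Bt-1 and -0.08 in Ye478, while lim1 stood at -1.64 and -1.41.

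Of the gene lists, 4 of 21 passed camera in Bt-1. Glutathione transferases, which conjugate glutathione to toxic compounds, were shifted upward with 19 of 31 genes positive and a median log2 change of 0.26 (adjusted p = 0.0256; adjusted p = 0.656 with an estimated correlation). None of the 31 brightest probe sets passed alone, and 5 passed when adjusted over the list alone. Among them GST25 had 4.50 and gst8 4.20, with limma adjusted p of 0.0535 and 0.0509. Both passed with array weights, with spike-in scaling, without the dimmest probe sets and without either infected Ye478 array, and gst8 also with quantile normalization and with a pseudocount of 1. Genes of the jasmonate and oxylipin pathway were shifted upward, with 8 of 10 positive (adjusted p = 0.0256; adjusted p = 0.656 with an estimated correlation). None passed alone and 1 passed adjusted over the list alone. The allene oxide synthase aos1 had 1.40 (adjusted p = 0.063) and opr1 2.05 (adjusted p = 0.188). Genes of terpenoid and phytoalexin synthesis were shifted upward, with 9 of 12 positive (adjusted p = 0.0330; adjusted p = 0.656 with an estimated correlation), 0 passing alone and 4 adjusted over the list alone. Of these, dxr had 2.25 (adjusted p = 0.0857), and 2.93 with a pass without Bt-1 infected replicate 1. The list of cell wall construction and loosening was shifted downward, with 5 of 25 genes positive and a median of -0.59 (adjusted p = 0.0256; adjusted p = 0.656 with an estimated correlation). In it xet1 fell and no gene rose, and 3 passed adjusted over the list alone. All 4 shifts lost their pass without Bt-1 control replicate 1, with adjusted p of 0.273, 0.353, 0.0649 and 0.0649 in the order given, and without Bt-1 infected replicate 1, with 0.0559, 0.0559, 0.0633 and 0.0559. Without Bt-1 infected replicate 2 the first 3 lost it (0.0934 each), and the median of the glutathione transferases was 0.0285. That median was 0.753 without Bt-1 infected replicate 1, 0.481 without Bt-1 control replicate 2, 0.860 without the dimmest probe sets, 0.15 with a pseudocount of 64 and 0.109 with spike-in scaling. The terpenoid shift also lost it without the dimmest probe sets (0.120) and without either infected Ye478 array (0.0561 and 0.0570). Of 5 benzoxazinoid genes only bx6 passed, and of 5 pathogenesis-related genes none did. The ratio of 3' to 5' ubiquitin control signals, a measure of RNA integrity, was 0.97 ± 0.03 on the log2 scale in control and 0.54 ± 0.06 in infected Bt-1 bracts (SD, n = 2). That of GAPDH was 1.19 ± 0.36 and 0.95 ± 0.03 and that of elongation factor 1-alpha 1.49 ± 0.22 and 1.35 ± 0.13. The cyclophilin ratio went the other way, from 0.70 ± 0.14 to 0.83 ± 0.08.

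In all, 198 of 17621 probe sets passed in Bt-1, of which 112 were higher and 86 lower after infection, and 2968 had an unadjusted p under 0.05 where chance gives 881. With arrays scaled to the hybridisation spike-ins, which shifted the median change by -0.22, 113 were higher and 161 lower. The count was 44 without Bt-1 control replicate 1, 76 without Bt-1 control replicate 2, 120 without Bt-1 infected replicate 2, 63 without Ye478 control replicate 1 and 64 without Ye478 control replicate 2. It was 306 with array weights and 6 when only the 4 Bt-1 arrays were fitted. Of the 17 named genes, all 17 lost their pass without Bt-1 control replicate 1, without Bt-1 control replicate 2 and with the 4 arrays alone, 12 without Bt-1 infected replicate 2, 14 without either Ye478 control array, 6 without Bt-1 infected replicate 1, 4 without either infected Ye478 array and 5 with spike-in scaling. With a pseudocount of 1, umi11 (limma adjusted p = 0.151), GA20 (0.0705), pip1e (0.131) and Lsi1 (0.0600) lost it, and with one of 64 ARLC did (0.0669). Between these pseudocounts ARLC went from 5.0, with a pass, to 1.27, waxy1 from 4.77 to 1.36, pip1e from -2.33 to -0.71 and Lsi1 from -2.31 to -0.71. The 2 infected Bt-1 arrays lay over 4-fold apart in 250 of all probe sets and those of Ye478 in 207. The log2 changes of the 17 genes kept their sign under every alternative. Since these genes were chosen for groups whose arrays did not overlap, only quantile normalization and spike-in scaling could have changed it.

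The same comparison in the susceptible line gave 11 probe sets, 10 higher and 1 lower, none of them with a usable gene name, and 2144 with an unadjusted p under 0.05. The probe set Zm.10022.1.A1_at rose from 83.1 to 2066 and Zm.17312.1.A1_at from 4.20 to 329, while Zm.694.1.A1_a_at fell from 304 to 29.4. In Bt-1, Zm.694.1.A1_a_at had 27.9 in control and 32.0 in infected bracts, so in Ye478 it fell to the Bt-1 level. The list of glutathione transferases was shifted upward, with 20 of 31 genes positive and a median of 0.31 (camera adjusted p = 0.0439; adjusted p = 0.729 with an estimated correlation). None passed alone and 3 passed adjusted over the list alone. The shift lost its pass with a pseudocount of 1 (0.0510) or 64 (0.0507), without Bt-1 control replicate 1 (0.0968), Bt-1 control replicate 2 (0.0964), Bt-1 infected replicate 2 (0.0506), Ye478 control replicate 2 (0.228) or Ye478 infected replicate 1 (0.212). Its median was 0.164 without Ye478 control replicate 2 and 0.135 with spike-in scaling. Of the cell wall list 8 of 25 genes were positive in Ye478, with a median of -0.11, and it did not pass (camera adjusted p = 0.610). Named genes that did not pass included an2, an ent-copalyl diphosphate synthase of phytoalexin synthesis, at 3.03 ± 0.76 (limma adjusted p = 0.211), the wound-induced proteinase inhibitor wip1 at 2.68 ± 0.69 (adjusted p = 0.225) and the hemoglobin GLB1 at 2.74 ± 0.69 (adjusted p = 0.213). The proline-rich protein plr354a had -1.72 ± 0.29 (adjusted p = 0.127), and -1.97 with spike-in scaling, where it passed. The count was 0 without Ye478 control replicate 2, 2 without either Bt-1 control array, 24 without Ye478 infected replicate 1, 48 without Ye478 infected replicate 2 and 0 with the 4 Ye478 arrays alone. With arrays scaled to the spike-ins, which shifted the median by -0.19, 12 were higher and 7 lower, and with quantile normalization 8 were higher and 2 lower. The count was 7 with a pseudocount of 1 or of 64. Without Ye478 control replicate 1, the probe sets that passed were more often lower than higher.

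**Figure D2:**
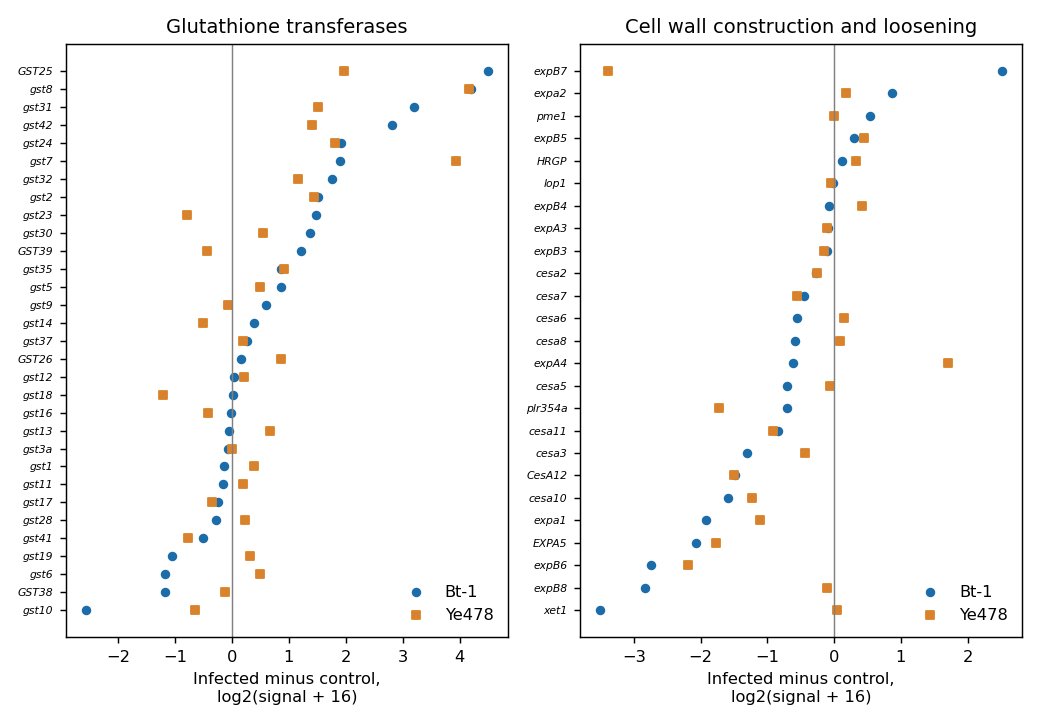
Log2 change of signal between infected and control bracts for each gene of the glutathione transferase list (left) and the cell wall list (right), in Bt-1 (circles) and Ye478 (squares), 1 probe set per gene. Of 31 glutathione transferases, 19 were positive in Bt-1 and 20 in Ye478, and of 25 cell wall genes, 5 were positive in Bt-1 and 8 in Ye478, where the cell wall list did not pass.

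Whether the lines differed in their response was tested by the interaction of line and infection. No named gene passed. The nearest of those named above were xet1, at -3.56 (adjusted p = 0.0724), GLN6, at 3.53 (adjusted p = 0.0845), and GA20, at -2.89 (adjusted p = 0.0954). None of the 21 lists passed, and the glutathione transferase list had an adjusted p of 0.965. In all, 19 probe sets passed, 8 with a larger value in Bt-1 and 11 with a smaller one, and 1554 had an unadjusted p under 0.05. The count was 0 without Bt-1 control replicate 1 or Ye478 control replicate 2, 7 without Bt-1 control replicate 2, 46 without Bt-1 infected replicate 1, 5 without Ye478 control replicate 1, 8 without Ye478 infected replicate 1 and 10 without Ye478 infected replicate 2. It was 12 with a pseudocount of 1 and 7 without the dimmest probe sets. At some of the 19 the lines differed in control bracts and the infected line came near the other's level. Zm.9571.1.A1_at went from 1757 to 197 in Bt-1, against 186 and 182 in Ye478. Zm.12345.1.A1_a_at went from 3.71 to 225 in Ye478, against 395 and 309 in Bt-1. There a genotype difference between infected and control plants is not told apart from a response. At others, such as Zm.6651.1.A1_at, control bracts did not differ past the threshold.

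The calls of both lines shared 2 higher probe sets and 0 lower ones. Independent lists would share 0.064 higher ones (one-sided Fisher's exact test across probe sets, which are not independent, p = 0.00174), a value that leaves out the variance per probe set that both tests share. Of the 112 probe sets called higher in Bt-1, 84 were also positive in Ye478, with a median of 0.49 there, and of the 86 called lower, 65 were also negative, with a median of -0.37, while 60.5% of all 17621 probe sets had the same sign in both lines. With all arrays but one, the shared count was 1 without any one of Bt-1 infected replicate 1, Bt-1 infected replicate 2 and Ye478 infected replicate 1, 0 without either control array of either line and 11 without Ye478 infected replicate 2.

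Averaged over both lines, several glutathione transferases were higher in infected than in control bracts. The gst8 signal went from 18.6 to 689 in Bt-1 and from 24.6 to 839 in Ye478, a mean log2 change of 4.18 ± 0.52 (SE; limma adjusted p = 0.0231). GST25 rose by 3.23, gst7 by 2.91 and gst31 by 2.35. The phytoalexin enzyme an2 rose by 2.94 ± 0.54 (adjusted p = 0.0446), FAD8 by 2.06 and cda2 by 1.66. The MYB factor myb42 rose by 1.90, with another probe set of opposite sign. The means of waxy1, 1.83, and GLN6, 1.69, also passed. Lower on average were the chlorophyll a/b-binding protein Cab-m7 at -1.84, AGP2 at -1.73, xet1 at -1.73, lkrsdh1 at -1.64, akh2 at -1.56, lim1 at -1.52, the MYB factor rs2 at -1.28, plr354a at -1.22, GR2b at -1.14 and the starch branching enzyme sbe1 at -1.14. The xet1 mean joined -3.51 in Bt-1 with 0.05 in Ye478, and that of GLN6 3.45 with -0.08. Of 31 glutathione transferases 5 rose and 0 fell, and 6 passed adjusted over the list alone (camera adjusted p = 0.0124; adjusted p = 0.448 with an estimated correlation). The shift lost its pass without Bt-1 control replicate 1 (0.128).

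For the mean effect 409 probe sets passed, 256 higher and 153 lower. With spike-in scaling, which shifted the median by -0.21, 133 were higher and 179 lower. The count was 32 without Bt-1 control replicate 1, 82 without Bt-1 control replicate 2, 159 without Bt-1 infected replicate 2, 30 without Ye478 control replicate 1, 21 without Ye478 control replicate 2 and 66 without Ye478 infected replicate 1. Of the 20 named genes, 20 lost their pass without Bt-1 control replicate 1, 18 without Bt-1 control replicate 2, 19 without Ye478 control replicate 1, 20 without Ye478 control replicate 2, 14 without Ye478 infected replicate 1, 11 without Bt-1 infected replicate 2, 6 without Bt-1 infected replicate 1 and 4 without Ye478 infected replicate 2. With a pseudocount of 64 an2 did not pass (limma adjusted p = 0.0532), nor did gst7 with one of 1 (0.0532). Between pseudocounts of 1 and 64 Cab-m7 went from -3.29 to -0.88 and waxy1 from 3.62 to 0.86, and with 64 rs2 had -0.82. Without single control arrays the mean change of gst8 lay between 3.92 and 4.44.

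Control bracts of the lines differed in many cell wall transcripts. The cellulose synthase CesA-4 had a signal of 3244 ± 239 in Bt-1 and 77.3 ± 30.5 in Ye478 (SD, n = 2), a log2 difference of 5.16 ± 0.41 (SE; limma adjusted p = 0.000907). The cellulose synthases cesa10, CesA12 and CesA-9 were higher in Bt-1 by 3.97, 3.93 and 3.77, and the expansins EXPA5 and expB8 by 3.87 and 3.36. CesA-4 and CesA-9 were not matched to the cell wall list by their symbols. In that list 13 of 25 genes were higher in Bt-1 and 0 lower, 15 adjusted over the list alone (camera adjusted p = 0.000961; adjusted p = 0.453 with an estimated correlation). In the list of histones and cell division 9 of 27 were higher and 0 lower, 10 adjusted over the list alone (adjusted p = 0.000961; adjusted p = 0.351 with an estimated correlation). Those 9 were the tubulins tub3, tub5, tub6, TUA1, tua5 and tua6, the histone his1a, the kinase cdc2 and the cyclotide gene umi11, which matched the list through a synonym. The ratio of 3' to 5' elongation factor 1-alpha control signals was 1.49 ± 0.22 in Bt-1 and 1.96 ± 0.23 in Ye478 control bracts on the log2 scale, and that of GAPDH 1.19 ± 0.36 and 1.33 ± 0.43 (SD, n = 2). That of cyclophilin was 0.70 ± 0.14 and 0.80 ± 0.19, while that of ubiquitin was higher in Bt-1, at 0.97 ± 0.03 and 0.78 ± 0.34. Also higher in Bt-1 were piip1 by 5.24, the heat shock protein hsp18f by 3.64, a probe set of tub5 by 3.46 and piip2 by 3.39. Between pseudocounts of 1 and 64 piip1 went from 8.08 to 3.48, and with 64 piip2 had 2.11.

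Transcripts lower in Bt-1 than in Ye478 controls were the protein disulfide isomerase pdi6 at -6.73, the terpene synthase TPS4 at -4.82, the cytokinin oxidase cko1 at -3.85, elfa2 at -3.42 and the tryptophan synthase orp2 at -3.07. Further down the list stood gst23, with signals of 104 and 942, and the response regulator RR6 at -2.94. Also lower were the dehydrin dhn1 at -2.91, the ribosome-inactivating protein rip2 at -2.83 and ciszog1, a cis-zeatin glucosyltransferase, at -2.72. Only 2 of the 4 other probe sets of elfa2 had its sign. The value of rip2 was -1.82 without Bt-1 control replicate 1 (limma adjusted p = 0.152), and rip2 did not pass without either Ye478 control array (0.177 and 0.0664), without either infected Ye478 array (0.0508 and 0.0509) or with the 4 arrays alone (0.0509). Without Ye478 control replicate 2, TPS4 had -2.87 and the expansin expB8 2.05. With a pseudocount of 64 TPS4 did not pass, at -3.23 (0.0632), and with one of 1 it had -7.26. Between these pseudocounts orp2 went from -5.43 to -1.61 and ciszog1 from -4.48 to -1.51. In all, 3053 probe sets differed, 1633 higher and 1420 lower in Bt-1. With spike-in scaling, which shifted the median by 0.32, 1964 were higher and 608 lower. The count was 823 without Bt-1 control replicate 1, 1283 without Bt-1 control replicate 2, 1183 without Ye478 control replicate 1 and 1323 without Ye478 control replicate 2. Of the 20 named genes, 11 passed under every alternative, and at most 8 lost their pass without a single array, Bt-1 control replicate 1. A sequence difference between the lines under a probe can change a signal without a change in RNA.

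In infected bracts the line difference included bx6, with a signal of 26.6 ± 11.4 in Ye478 (SD, n = 2) and a log2 difference of 4.88 ± 0.33 (SE; limma adjusted p = 0.00056). The terpene synthase TPS9 was higher in Bt-1 by 5.04, umi11 by 4.24, gst18 by 3.62, CesA12 by 3.95, CesA-9 by 3.65, cesa10 by 3.61, piip1 by 3.60, tub5 by 3.57 and EXPA5 by 3.57. Lower in Bt-1 were orp2 at -3.69, cko1 at -2.68, GT1 at -2.41, xet1 at -2.25, ciszog1 at -2.24, the anthocyanin regulator c1 at -2.04, bsd2 at -2.02, gst28 at -1.82, ptk1 at -1.71 and the phototropin nph1 at -1.66. Of the histone and cell division list 8 of 27 were higher and 0 lower, 11 adjusted over the list alone (camera adjusted p = 0.00218; adjusted p = 0.380 with an estimated correlation). Of the cell wall list 8 of 25 were higher and xet1 was lower, and camera did not pass (adjusted p = 0.0692). The ratio of 3' to 5' GAPDH control signals was 0.95 ± 0.03 in Bt-1 and 1.31 ± 0.07 in Ye478 infected bracts on the log2 scale, and that of ubiquitin 0.54 ± 0.06 and 0.56 ± 0.25 (SD, n = 2). That of elongation factor 1-alpha was 1.35 ± 0.13 and 1.59 ± 0.32, and that of cyclophilin 0.83 ± 0.08 and 0.78 ± 0.25.

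In infected bracts 2238 probe sets passed, 1176 higher and 1062 lower in Bt-1. With spike-in scaling, which shifted the median by 0.28, 1150 were higher and 357 lower. The count was 602 with the 4 infected arrays alone, 1464 without either Bt-1 control array, 1211 without Bt-1 infected replicate 1, 1148 without Bt-1 infected replicate 2, 1215 without Ye478 infected replicate 1 and 954 without Ye478 infected replicate 2. With a pseudocount of 1 ciszog1 did not pass (limma adjusted p = 0.126) and piip1 had 5.97. With one of 64 piip1 had 2.10, umi11 2.72, EXPA5 2.34, orp2 -2.41 and c1 -1.14, and all 5 passed. Of the 20 named genes, 8 passed under every alternative, and at most 10 lost their pass without a single array, Ye478 infected replicate 1. The control and infected line differences had 768 higher and 625 lower probe sets in common. Independent lists would share 109 and 85.6, which is not the value without effects, since both tests used the same variance per probe set, estimated from all 8 arrays.

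**Figure D3:**
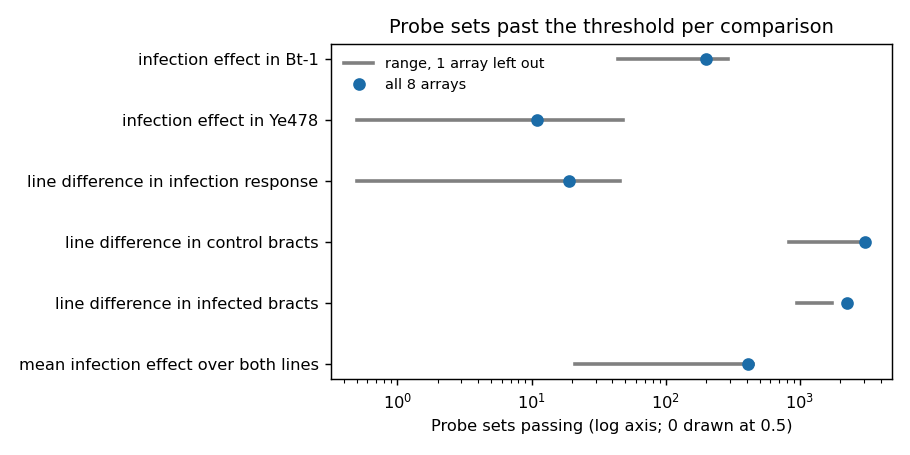
Number of probe sets past the limma threshold in each comparison on a log axis, with all 8 arrays (circles) and the range when 1 array was left out (bars; a count of 0 is drawn at 0.5). The infection effect gave 198 in Bt-1 and 11 in Ye478, and the line difference in control bracts 3053.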

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

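The scaling to spike-ins, the ratio of replicate variances and the test of a difference in response were chosen after the counts had been seen. The interaction of line and infection passed in 19 probe sets with all 8 arrays, a count that depended on single arrays. The largest values in each direction follow, 1 per transcript cluster. Of these, Zm.16049.1.S1_at had an interaction of 5.98 on the log2 scale, with a signal of 1.53 in control and 1336 in infected Bt-1 bracts and of 3.05 and 7.51 in Ye478. Zm.3225.1.S1_at had 4.76, from 41.2 to 1853 in Bt-1 and 2683 to 3307 in Ye478. Zm.6651.1.A1_at had -5.24, from 9926 to 281 in Bt-1 and 11982 to 13210 in Ye478. Zm.17312.1.A1_at had -4.56, from 7.35 to 1.04 in Bt-1 and 4.20 to 329 in Ye478. The hybridisation spike-ins, which the comparisons do not use, were brighter on infected than on control arrays, by 0.28 in Bt-1 and 0.25 in Ye478 on the log2 scale. That is within the spread of the control arrays, whose SD was 0.38 in Bt-1 and 0.27 in Ye478.

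Infection passed in 198 probe sets in Bt-1 and 11 in Ye478. The scaling of the arrays stays open. Counts scaled to the spike-ins stood at a ratio of 14.4. That scaling shifted the median change nearly alike in both lines, by -0.22 in Bt-1 and -0.19 in Ye478. It could therefore hardly change the contrast of the lines, and does not decide the question. A larger spread in Ye478 could not lower its count through the standard error, since the fit gave both lines the same one per probe set. The replicate variance of Ye478 was 0.987 times that of Bt-1 (1.12 times in control and 0.907 times in infected bracts), a ratio that for this reason does not test the explanation. A difference in response between the lines stays open: the variance of the effects after subtraction of the replicate variance, the test of spread first set, which had left it open, was 2.29 times as large in Bt-1, but 1.15 times without Bt-1 control replicate 1, 1.24 times without Ye478 infected replicate 2, 3.51 times without Bt-1 infected replicate 1 and 6.61 times without Ye478 control replicate 2. Likewise 19 probe sets passed the interaction, but 0 without Bt-1 control replicate 1 or Ye478 control replicate 2, 7 without Bt-1 control replicate 2, 46 without Bt-1 infected replicate 1, and 5, 8 and 10 without Ye478 control replicate 1, infected replicate 1 and infected replicate 2.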

How the results depend on the processing

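The alternative chosen after the data had been seen was the scaling to spike-ins. With 2 arrays per group, the counts depended on single arrays. With 1 array left out they ranged from 44 to 292 for infection in Bt-1, 0 to 48 in Ye478, 0 to 46 for the interaction, 823 to 3149 for control bracts, 954 to 1727 for infected bracts, 21 to 444 for the mean effect, 0 to 11 for the shared calls and 6 to 14 for the lists. With only the 4 arrays compared they fell to 6 in Bt-1, 0 in Ye478 (limma) and 602 in infected bracts, but rose to 3320 in control bracts. Array weights gave 306 in Bt-1 and 1 shared call. A pseudocount of 1 gave 7 in Ye478, 12 for the interaction and 1 shared call, and one of 64 gave 7 in Ye478 and 1 shared call. Quantile normalization gave 1 shared call, the filter on dim probe sets 7 for the interaction, and spike-in scaling 19 in Ye478. Of the lists, 0 passed with an estimated correlation and 14 with all probe sets of a gene. The cause was not tested. Between 17.4% and 19.0% of the values of an array were under 16, where the pseudocount limits the change that can be measured. Same-numbered arrays of different groups deviated together with a correlation between -0.04 and 0.03, so the numbers do not pair the arrays. With the number as a replicate block the counts were 143 in Bt-1, 2 in Ye478, 5 for the interaction, 2526 in control and 1681 in infected bracts, 177 for the mean effect and 0 shared calls, and 8 lists passed (the glutathione transferases in Ye478 were lost, adjusted p = 0.0763). Of the named genes, 7 of 17 in Bt-1, 10 of 20 for the mean effect, 1 of 20 in control and 0 of 20 in infected bracts did not pass with the block (rip2 in control bracts, adjusted p = 0.0515). With a pseudocount of 1 or 64 the value moved by over 1.5 times for 4 named genes in Bt-1, 5 in control bracts, 5 in infected bracts and 3 for the mean effect. Of 77 calls of named genes, 19 held under every alternative run, all 19 of them line differences, and 77 kept their sign. Outside the mean effect, the rule of selection left only quantile normalization and spike-in scaling able to change a sign. Among genes that had not passed, the value of chn1 in Bt-1 became -0.0599 without Bt-1 control replicate 1 and 1.71, with a pass, without Bt-1 control replicate 2, and that of prf5 in Ye478 became -0.00065 with quantile normalization and -0.0745 with spike-in scaling.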

Other observations

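The test of a fall of cell division was chosen after its result had been seen, as were the covariance that mixed RNA would give and the count of probe sets far apart on 2 infected arrays. That covariance replaced a requirement first set for the test of mixed RNA, that the quartiles not exceed those of held-out control arrays, which was not met, and the bounds of that test were chosen after those first set had left 1 probe set. The kernel markers, 28 genes with some that other tissues express, did not pass in Bt-1 (camera adjusted p = 0.592), where waxy1 alone rose, nor in Ye478 (adjusted p = 0.610). None of the 3 pollen and anther genes passed in either line. The mean infection effect passed in 409 probe sets, and of the 18 ways to exchange infected and control arrays within lines, 1 gave as many, the real one, while the highest other gave 19. These splits are too few for a share under 0.05.

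Many probe sets differed between the lines in control bracts. Sequence differences under single probe sets stay open as a source. Of 51 genes with another probe set, 86.3% had the same sign in both (95% exact interval 73.7% to 94.3%). Of the second probe sets, 22 also passed. Probe sets of a gene that overlap would share such a difference and its sign, so these values do not decide the question. The 51 genes also stand for few of the 3053 probe sets, of which 245 had a usable gene name. Sequence differences shared by all probe sets of a gene, or by probe sets that overlap, may contribute. They cannot be told apart from RNA differences here, since both predict the same sign in infected bracts, which 94.0% of the calls had.

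Over probe sets, the Bt-1 infection effect had a covariance of 0.252 with the Ye478 minus Bt-1 control difference, where unchanged groups gave 0.0757 in 50 simulations, so infected Bt-1 bracts lay nearer to the Ye478 level (the like covariance in Ye478 was 0.0674, against 0.0766 simulated). Single probe sets went the other way, such as Zm.694.1.A1_a_at, which fell to the Bt-1 level in infected Ye478 bracts. Noise of a single shared control array is argued against as the whole source. The Bt-1 covariance was 0.193 and 0.200 when each side used another Bt-1 control array. A shift common to both Bt-1 control arrays would remain in both differences. The split does not test such a shift, which stays open. Ye478 RNA in the infected Bt-1 samples is argued against as the whole source: over 13 probe sets under 16 in both Bt-1 and over 500 in both Ye478 controls, the lower quartile was 0.436% and 0.523% of the Ye478 level, above the 0.236% and 0.213% of held-out Bt-1 control arrays but under the 2% set beforehand, a share that would give a covariance of only 0.037, while the medians were 0.937% and 2.27% and single values ran from 0.0318% to 97.1%. Genotype differences between the infected and the control Bt-1 plants may be involved and stay open, as the rank correlation of neighbouring genes was -0.0143 over 241 genes, inside the permuted range of -0.13 to 0.12, which decides nothing. A fall of cell division, the biological explanation tested, also stays open (median -0.23, camera adjusted p = 0.509). The same list had a median of -0.26 in Ye478 (camera adjusted p = 0.247), so a like shift, also short of the threshold, was seen there.

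Of those 13 probe sets, 7 lay over 4-fold apart on the 2 infected Bt-1 arrays, 2 of them higher on replicate 1 and 5 on replicate 2. In the opposite case, 1 of 2 probe sets lay as far apart on the infected Ye478 arrays. On the 2 infected Bt-1 arrays, pdi6 had signals of 14.8 and 1307, against means of 11.5 in Bt-1 and 2898 in Ye478 control bracts.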
